A study of Arabidopsis thaliana with 6 samples.

How the data were processed

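RNA from whole seedlings of Arabidopsis thaliana, accession Columbia, was hybridised to 6 Affymetrix ATH1 arrays, 1 per sample. Per the labels, seedlings grew for 13 days in shaken liquid medium, 10 per flask of 100 ml, under a 16 h photoperiod. They were then dosed for 6 h with 2,4,6-trinitrotoluene (TNT) at 60 µM dissolved in dimethylformamide (DMF), or with 60 µl of DMF alone. There were 3 arrays per group. The labels do not say whether replicates came from separate flasks, so p-values measure the spread between these samples, which may be technical. Replicate numbers were taken from the sample titles. The title of 1 TNT sample carries no number, and it was called replicate 1 because numbers 2 and 3 were taken.

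The deposited intensity values are linear probe set signals made by the authors with MAS5 and GCOS, per the submitters' processing notes. Versions and scan settings were not given in the sources used here. The mean of each column without its top and bottom 2% of values lay at 100.01 on each array, so each array had been scaled to a common level before deposit. MAS5 subtracts mismatch signal, so low values spread widely on a log scale, and a scaling to a common mean cannot show a change in total RNA. The value table held no detection calls, so the highest signal among control probe sets for bacterial genes, which lay between 6.34 and 14.3 across arrays, was taken as a floor. Where all DMF signals of a gene lay under it, a fold is given as a lower bound against that floor. No 2 arrays shared a column of identical values.

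Of 22810 probe sets, 64 controls were left out. The platform annotation paired 13513 of the other 22746 with 1 gene, 503 with several genes, and left 8730 without a name here. Symbols were updated through gene identifiers to the TAIR10.1 reference table, where 13436 of the 1-gene probe sets had a match. No gene was named from a probe set that this annotation pairs with several genes. Whether the probes of a 1-gene probe set also match transcripts of other genes was not examined. Genomic coordinates are not given, since the sources name no genome build.

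Signals were taken to log2 without an offset and without further normalization. Probe sets whose mean over the 6 arrays lay at or above the 40th percentile were tested, which left 13648. TNT was compared with DMF with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference of 1 marks 2-fold. There were 22 gene lists fixed beforehand, with 1 probe set per gene, and those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the 7 lists that qualified. Camera with an estimated correlation and fry were run beside it. The ABC transporter and nitrate lists had 0 tested genes. Symbol families with at least 4 tested genes were tested with Fisher's exact test, two-sided. Array controls were compared with an exact permutation test, which with 3 against 3 arrays cannot give a p under 0.1.

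The genes to be named were set by a rule fixed before the data were examined. It took the 8 genes of a list of TNT-converting enzymes, the 10 highest and 10 lowest log2 differences among called genes with a symbol and groups that did not overlap, and up to 4 members of each list by p. The second part gave 0 genes in the comparison of all 6 arrays. After the values had been seen it was applied to the comparison without the array labelled TNT replicate 2, where it gave 20 genes.

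Alternatives chosen before the data were examined were no filter, a filter at the 60th percentile, an offset of 16 before log2, quantile normalization, median centring, no intensity trend, array weights, the replicate number as a block, each array left out in turn, an estimated correlation, and only 1-gene probe sets. Leaving out both arrays numbered 2, and every alternative of the comparison without TNT replicate 2, were added after seeing the data. The replicate numbers pair the samples by their deviations from the group means, which correlated across probe sets at 0.54, 0.47 and 0.43 for numbers 1, 2 and 3. Where the pairing comes from is not stated in the labels.

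The fit was tested on simulated data with 200 changed probe sets among 13648, drawn 5 times on the real means and spread. For the comparison of all 6 arrays it recovered 2.69% of 1.5-fold, 37.3% of 2-fold and 90.0% of 4-fold changes, with 5.69% of calls false. For the comparison without TNT replicate 2 it recovered 4.18%, 51.9% and 97.6%, with 5.56% false. The simulated noise was independent between probe sets and arrays, and each change was added in full to every TNT array. The real arrays pair by replicate number, and TNT replicate 2 lay near the DMF arrays, so these rates can be too favourable for them. A shift of 0.4 in the glycosyltransferase list passed at an unadjusted p of 0.05 in 5 of 5 runs in either comparison; without the shift 1 of 5 and 0 of 5 runs passed. Figures were drawn with matplotlib 3.10.9.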

Results

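Transcript levels were measured on ATH1 arrays in whole Arabidopsis seedlings dosed for 6 h with 60 µM TNT, a nitroaromatic explosive, in 3 samples, and in 3 samples given the solvent DMF. The comparison asks which transcripts differ after exposure to TNT. Median signals over non-control probe sets lay between 40.1 and 50.8 on the MAS5 scale, and between 73.8% and 80.7% of probe sets exceeded the highest bacterial control on their array. The number of arrays, 3 per group, limits the precision.

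GSTU25, GSTU22, UGT73B5 and NDB2 had higher signals on the arrays labelled TNT replicates 1 and 3 than on any DMF array, while the array labelled TNT replicate 2 stayed nearer to the DMF arrays. GSTU25 (AT1G17180), a tau-class glutathione S-transferase, had a log2 signal of 3.86 ± 0.41 (SD, n = 3) with DMF and 8.90, 4.78 and 9.05 on TNT replicates 1, 2 and 3. UGT73B5 (AT2G15480), a UDP-glycosyltransferase, stood at 3.82 ± 0.35 (SD, n = 3) with DMF and at 7.81, 4.43 and 8.32 with TNT. With all 6 arrays the log2 difference of GSTU25 was 3.72 ± 1.02 (SE), with a limma adjusted p of 0.477. The spread among the TNT arrays was thus too wide for a call. No probe set passed in limma over all 6 arrays (0 of 13648), while 1195 had an unadjusted p under 0.05 against 682.4 expected by chance. With the replicate number as a block 0 passed as well, with 2311 at the unadjusted threshold. Groups did not overlap for 12.3% of probe sets, and chance gives 10%.

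Array correlations over the tested probe sets (across probe sets, which are not independent) placed TNT replicate 2 with DMF replicate 2, at r = 0.975. TNT replicates 1 and 3 correlated at 0.969 with each other, and at 0.888 and 0.906 with TNT replicate 2. The comparison without TNT replicate 2 was planned as an alternative, not as the main comparison. In it 947 probe sets passed in limma, of which 504 rose and 443 fell. At least 2-fold changes numbered 334 upward and 229 downward. Of the 947, 444 match 1 gene and 487 are unnamed here. With the replicate number as a block, DMF replicate 2 has no partner, which leaves 1 residual degree of freedom. The number was 3733 in that fit and 2897 with array weights. It fell to 386 when DMF replicate 3 was left out too, to 179 without TNT replicate 1 and to 202 without TNT replicate 3, where 1 TNT array is assumed to vary like the DMF arrays. Calls given from here on as rose or fell are those of limma without TNT replicate 2, a basis taken after the values had been seen. Leaving out an array for its values narrows the spread within TNT, so the p-values of these calls can be too small. None of these calls passed in the unweighted comparison of all 6 arrays. Array weights, planned beforehand and estimated from the same arrays, gave 2896 calls over the 6. The weights were 5.00 on DMF replicate 3 and 2.78 on TNT replicate 3. On the others they were 0.84 or less, with the lowest, 0.26, on TNT replicate 2. DMF and TNT replicate 3 thus carried most of the weight.

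**Figure D1:**
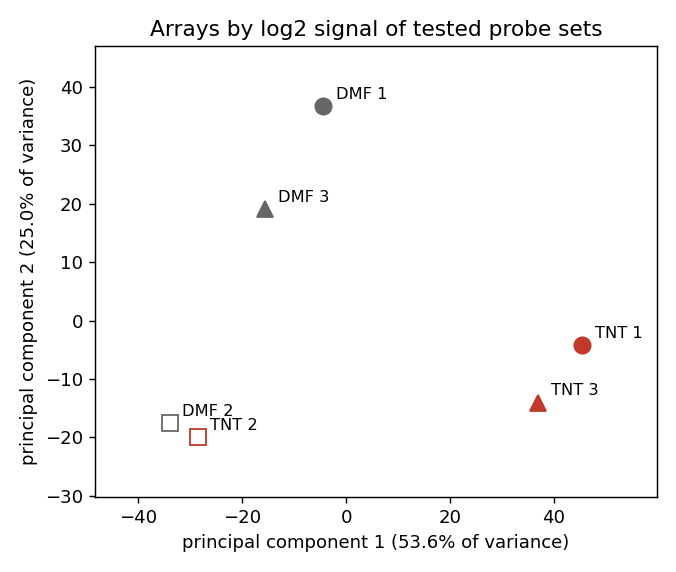
Scores of the 6 arrays on principal components 1 and 2 of log2 signal over 13648 tested probe sets (axes in score units, with 53.63% and 24.96% of the variance); grey marks are DMF, red marks TNT, and circles, open squares and triangles are replicates 1, 2 and 3. TNT replicates 1 and 3 score 45.5 and 37.0 on the first component, while TNT replicate 2 scores -28.6, between DMF replicate 2 at -33.9 and DMF replicate 3 at -15.5.

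Among enzymes known to act on TNT, GSTU25, which conjugates TNT to glutathione, rose 34.7-fold (adjusted p = 6.56e-05). Its DMF signals of 10.5, 18.2 and 15.9 lay near the bacterial controls (6.34, 14.3 and 9.19), so the size of this fold is uncertain. UGT73B4 (AT2G15490) and UGT73C1 (AT2G36750), glycosyltransferases that act on reduction products of TNT, were under the filter on low signal. UGT73B4 had signals of 0.51, 0.74 and 0.82 in DMF replicates 1, 2 and 3, all under the bacterial controls, and of 133.5, 1.44 and 134.3 in TNT replicates 1, 2 and 3. Without TNT replicate 2 and without the filter it was at least 14.2-fold higher with TNT. The limma adjusted p of 0.000344 belongs to a log2 difference of 7.63 on the deposited signals, not to this bound. For UGT73C1 the DMF signals were 0.32, 1.40 and 0.54 and the TNT signals 29.4, 1.86 and 19.3. UGT73C1 was at least 2.53-fold higher without TNT replicate 2. Its limma adjusted p of 0.0136 likewise belongs to a log2 difference of 5.27, not to the bound. Both p-values rest on log2 values of DMF signals under the floor. Over all 6 arrays without the filter the adjusted p was 0.629 and 0.594 for UGT73B4 and UGT73C1. The other 5 genes of this list were not analysed here, as no probe set is paired with them alone. The study group may have chosen list members on samples like these, so their direction is not independent evidence.

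The glycosyltransferase list, enzymes that attach sugars to small molecules, was higher with TNT over all 6 arrays. Its 27 genes had a mean log2 difference of 0.39 and a median of 0.07, with 17 positive (camera adjusted p = 0.0387, fry adjusted p = 0.205). The call was lost with an estimated correlation (adjusted p = 0.509), with array weights (adjusted p = 0.123), without DMF replicate 2 (adjusted p = 0.114) and without TNT replicate 1 (adjusted p = 0.165). No member passed alone over all 6 arrays; adjusted over the list alone, 1 rose. With TNT replicate 2 left out, the mean was 0.49 (camera adjusted p = 0.0173; adjusted p = 0.254 with an estimated correlation), 5 rose, 0 fell and 22 did not pass, and adjusted over the list alone 8 rose. UGT73B5 rose 19.0-fold, UGT87A2 (AT2G30140) 5.84-fold, UGT73B1 (AT4G34138) 5.38-fold and UGT74D1 (AT2G31750) 3.05-fold. The fold of UGT73B5 rests on DMF signals of 17.3, 10.8 and 15.1. That of DMF replicate 2 lay under the highest bacterial control of its array. UGT84A3 (AT4G15490) rose 2.94-fold at the edge of the threshold (adjusted p = 0.04998). IAGLU (AT4G15550), an indole-3-acetate glucosyltransferase not matched by the list, rose 4.34-fold (adjusted p = 0.00681).

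Glutathione S-transferases went both ways. Over all 6 arrays the 10 tested genes had a mean log2 difference of 0.33 but a median of -0.10, and camera ranked them downward (adjusted p = 0.665), so mean and test differ in sign. Adjusted over the list alone, 2 rose and 2 fell. In the 5-array comparison without TNT replicate 2, GSTU25 and GSTU22 (AT1G78340) rose, the latter 11.7-fold (adjusted p = 0.000273). GSTU18 (AT1G10360) fell 2.84-fold, while GSTU28 (AT1G53680) fell by 1.40 (adjusted p = 0.0475; 0.0655 without both arrays numbered 2) and GSTU26 (AT1G17190) fell by 1.00 on the log2 scale. The other 5 did not pass, among them GSTU16 (AT1G59700) at a log2 difference of 0.77, and adjusted over the list alone 3 rose and 4 fell.

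**Figure D2:**
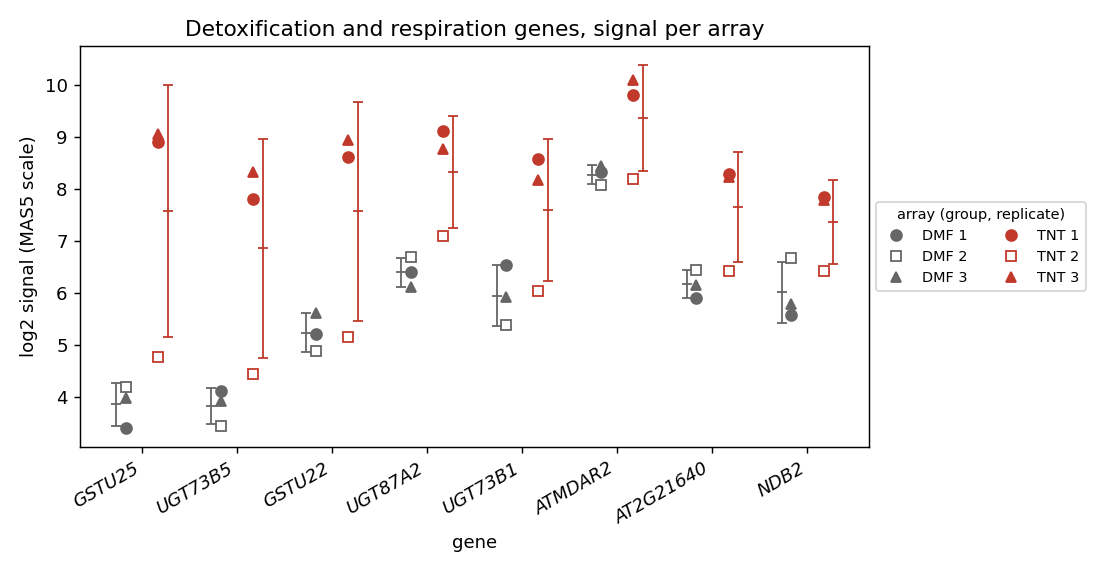
Log2 signal (vertical axis, MAS5 scale) of 8 genes (horizontal axis) on each array; grey is DMF, red TNT, circles, open squares and triangles are replicates 1, 2 and 3, and bars give the mean ± SD of 3 arrays. TNT replicates 1 and 3 lie above every DMF array for each gene, and TNT replicate 2 lies near the DMF arrays, for GSTU22 at 5.15 against a DMF mean of 5.23.

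Genes of mitochondrial stress rose in 2 of 3 tested members without TNT replicate 2. AT2G21640, a marker of mitochondrial oxidative stress, rose 4.25-fold (adjusted p = 0.0011). NDB2 (AT4G05020), an external alternative NAD(P)H dehydrogenase, rose 3.52-fold (adjusted p = 0.0149), while NDB1 differed by -0.02 on the log2 scale and did not pass. Over all 6 arrays the 3 had a mean log2 difference of 0.93, and none passed; adjusted over the list alone, 2 rose. Of 6 antioxidant genes, ATMDAR2 (AT5G03630), a monodehydroascorbate reductase, rose 3.20-fold and 5 did not pass, with GR1, a glutathione reductase, at 0.30. Over all 6 arrays this list had a mean of 0.24 (camera adjusted p = 0.168; adjusted p = 0.548 with an estimated correlation). It passed without DMF replicate 3 (adjusted p = 0.0463), which was not rerun with an estimated correlation. Of 9 cytochrome P450 genes, CYP71B23 (AT3G26210) rose 2.42-fold and 8 did not pass, with CYP71B26 at -0.69. That list had a mean of 0.07 over all 6 arrays (camera adjusted p = 0.669).

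Other genes with large rises were SUFE2 (AT1G67810), an activator of plastid cysteine desulfurase, which rose by 3.58 on the log2 scale, and WRKY6 (AT1G62300), a transcription factor of senescence and phosphate starvation, which rose 7.04-fold. AER (AT5G16970), an alkenal reductase, rose 5.00-fold and OCT5 (AT1G79410), of the organic cation transporter family, 4.71-fold. AER had log2 signals of 6.57, 6.36 and 6.63 with DMF and 8.76, 5.98 and 8.92 with TNT in replicates 1, 2 and 3.

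HRGP1 (AT3G54590), a hydroxyproline-rich wall protein, fell by 1.65 on the log2 scale (adjusted p = 0.00732), GH9C1 (AT1G48930), an endoglucanase, fell by 1.52 and EXPA18 (AT1G62980), an expansin of root hairs, fell by 1.35. HRGP1 was lower in every pair, by log2 differences of -1.54, -1.65 and -1.32 in replicates 1, 2 and 3, and over all 6 arrays it had a difference of -1.502 ± 0.24 (SE) that did not pass (adjusted p = 0.320; 0.0803 with the replicate block). The 13 expansin and xyloglucan endotransglucosylase genes had a mean log2 difference of -0.28 over all 6 arrays (camera adjusted p = 0.0806), which passed with the replicate block (adjusted p = 0.0192), with array weights (adjusted p = 0.0296) and without DMF replicate 3 (adjusted p = 0.0463). With an estimated correlation over all 6 arrays the camera adjusted p was 0.619, and the fry adjusted p was 0.545. The mean was -0.55 without TNT replicate 2 (camera adjusted p = 0.00652, or 0.254 with an estimated correlation, and fry adjusted p = 0.0625). In that comparison 2 fell, 0 rose and 11 did not pass, among them EXPA7 at -1.22. The list stood higher on both arrays numbered 2, at mean log2 signals of 7.06 with DMF and 7.04 with TNT, than on the other 4 (6.20 to 6.69). Its mean difference was -0.34, -0.03 and -0.48 in replicates 1, 2 and 3, and -0.41 without both arrays numbered 2 (adjusted p = 0.0119). The root list, a check on the share of root tissue, had a mean of -0.49 over its 4 tested genes with all 6 arrays and of -0.66 without TNT replicate 2, and was lower in each pair (-0.66, -0.31 and -0.51). EXPA18 and EXPA7 stand in both lists, while PYK10, an abundant root glucosidase, differed by 0.01, and 3 of the 4 did not pass.

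ECS1 (AT1G31580), a cell wall protein, fell by 2.42 on the log2 scale without TNT replicate 2 (adjusted p = 0.0243), from DMF signals that ranged from 8.31 to 10.26. NdhN (AT5G58260), a subunit of the plastid NADH dehydrogenase-like complex, fell by 1.63 and AOR (AT1G23740), a plastid alkenal reductase, fell by 1.31. STOMAGEN (AT4G12970), a peptide that raises stomatal density, fell by 1.26 and matK, the plastid intron maturase, fell by 1.16. This comparison keeps DMF replicate 2 without its partner. Without both arrays numbered 2 the log2 differences were smaller for AOR (-1.02), STOMAGEN (-1.08) and matK (-1.04), and larger for NdhN (-1.67) and ECS1 (-2.94).

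**Figure D3:**
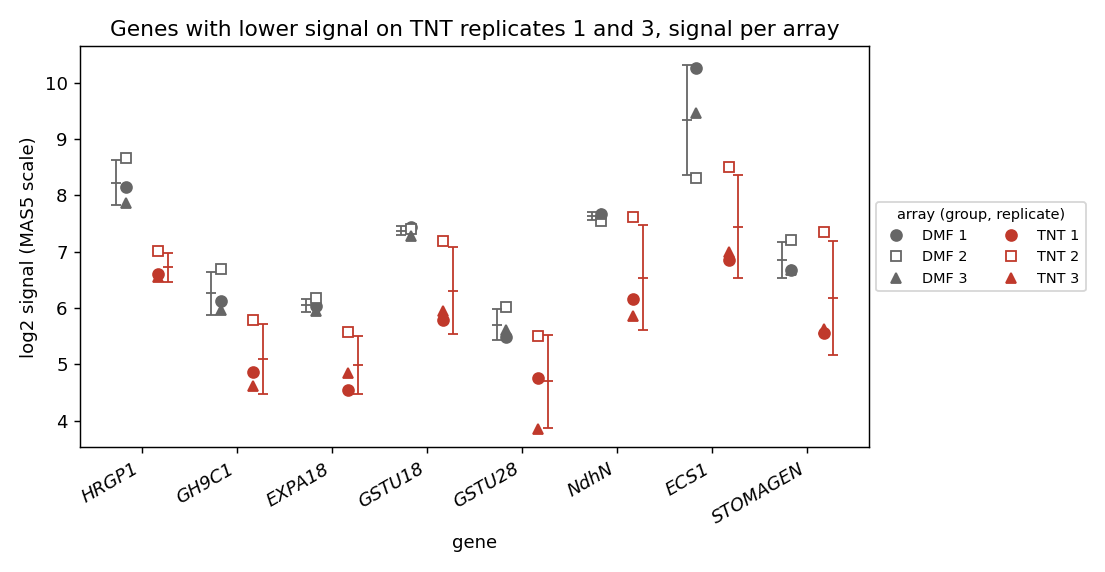
Log2 signal (vertical axis, MAS5 scale) of 8 genes (horizontal axis) on each array; grey is DMF, red TNT, circles, open squares and triangles are replicates 1, 2 and 3, and bars give the mean ± SD of 3 arrays. HRGP1 is at 7.02 on TNT replicate 2, under the lowest DMF array at 7.87, whereas NdhN is at 7.61 there, within the DMF range of 7.55 to 7.68.

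The photosynthesis list, 20 of whose 28 tested genes are plastid-encoded, had a mean log2 difference of -0.17 over all 6 arrays (camera adjusted p = 0.168; adjusted p = 0.683 with an estimated correlation). It passed without DMF replicate 2 (adjusted p = 0.0349) and without TNT replicate 3 (adjusted p = 0.0106), and its mean was positive, 0.11, without TNT replicate 1. Its mean was -0.31 without TNT replicate 2, and PRK (AT1G32060), phosphoribulokinase of the Calvin cycle, fell by 0.71 while 27 did not pass, with psaC of photosystem I at -1.54. The ribosomal protein list was meant for cytosolic ribosomes, but 14 of its 15 tested genes are plastid-encoded. It was lower with TNT over all 6 arrays by a mean of -0.36 (camera adjusted p = 0.0122, fry adjusted p = 0.516). The camera call was lost with an estimated correlation (adjusted p = 0.548) and without TNT replicate 1 (adjusted p = 0.265). Some plastid genes of both lists spread widely over DMF replicates 1, 2 and 3. Log2 signals there were 6.39, 8.03 and 9.50 for psaA and 8.21, 6.64 and 6.08 for rpl36. Others did not, as rpl33 at 10.91, 11.03 and 10.89. Without TNT replicate 2, rps16 fell by 1.09 (adjusted p = 0.0490; 0.0734 without both arrays numbered 2), 0 rose and 14 did not pass, including rpl22 at -0.58 and the nuclear gene AT1G77750 at -0.27.

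Lists with fewer than 5 tested genes were not put to a list test, and their values follow without TNT replicate 2. In the cell cycle list, PRL (AT4G02060), a replication licensing factor, fell by 0.87 and 2 did not pass. In the auxin list, GH3.17 (AT1G28130), an auxin-conjugating enzyme, fell by 0.85 and 3 did not pass, with IAA18 at 0.61. In the dehydration list, LTI30 (AT3G50970), a dehydrin, rose 2.67-fold and COR47 at 0.05 did not pass. None of 3 sulphate assimilation genes or 4 jasmonate genes passed, with mean log2 differences of -0.18 and -0.03. The 3 heat shock genes did not pass either, and their mean of 0.05 includes DMF replicate 2, where the list was high (7.41 against 5.84 and 5.92 on DMF replicates 1 and 3). Their mean difference was 0.62, -0.12 and 0.50 in replicates 1, 2 and 3, and without both arrays numbered 2, an alternative chosen after seeing the data, Fes1A was higher by 0.83 (adjusted p = 0.0347) and AT5G48570 by 0.82 (adjusted p = 0.0532). SAG101 of the salicylate list (1.03), PYE of the iron list (-0.03), PDC2 of the low-oxygen list (0.07) and GI of the clock list (-0.03) did not pass. Of 44 symbol families, 0 passed with Fisher's exact test. The smallest adjusted p, 0.0567, was that of 3 of 7 GH genes and of 3 of 8 GSTU genes that fell, and 5 of 25 UGT genes rose (adjusted p = 0.137). The GH symbols join unrelated genes, the endoglucanases GH9C1 and GH9C2 and the auxin-conjugating GH3.17.

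Array controls gave a measure of RNA quality. The ubiquitin ratio of 3′ to 5′ signal was 0.85 ± 0.02 with DMF and 0.67 ± 0.05 with TNT on the log2 scale (SD, n = 3), with an exact permutation p of 0.1, the smallest possible. Actin stood at 0.51 ± 0.18 and 0.51 ± 0.01 (exact permutation p = 1). GAPDH stood at 0.05 ± 0.13 with DMF and 0.08 ± 0.10 with TNT (exact permutation p = 0.7). The SD of log2 signal over tested probe sets was 1.33 and 1.34 on DMF and TNT replicate 2, and between 1.44 and 1.51 on the other 4 arrays.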

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

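The control probe set for 25S ribosomal RNA lies outside the comparisons, and was picked out because 1 TNT array exceeded the highest DMF array. Its signal was 965.5 on TNT replicate 1 and 696.4 on DMF replicate 1, against 13.7 and 26.3 on DMF replicates 2 and 3, and 39.4 and 26.7 on TNT replicates 2 and 3. Both arrays numbered 1 thus carried more of it. Groups of 3 are too small for a test of single outlying arrays.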

How the results depend on the processing

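Leaving out both arrays numbered 2, and each alternative of the comparison without TNT replicate 2, were chosen after seeing the data; the rest were planned. Over all 6 arrays the count of 0 called probe sets stayed at 0 with no filter, the 60th percentile filter, the offset, quantile normalization, median centring, no intensity trend, the replicate block and 1-gene probe sets. Array weights gave 2896 calls, 639 of them at least 2-fold, with weights of 0.26 for TNT replicate 2 and 5.00 for DMF replicate 3. With single arrays left out the count ranged from 0 to 947, and at least 2-fold from 0 to 563. It was 3 without DMF replicate 2 and 947 without TNT replicate 2. Without both arrays numbered 2 it was 1374 (656 at least 2-fold), and 907 of the 947 were shared, all with the same sign. A share of calls that rose has no value over all 6 arrays, as nothing was called.

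Without TNT replicate 2, the count of 947 ranged from 179 to 1374 with a further array left out, and the count of 563 at least 2-fold from 179 to 656. Array weights gave 2897, and the replicate block 3733 on 1 residual degree of freedom. With 1-gene probe sets the counts were 407 and 248, since fewer probe sets are tested there. The other settings gave between 750 and 972. The share that rose, 53.2%, ranged from 50.7% to 69.3% with a further array left out, and was under that range with array weights (46.6%) and with the replicate block (47.0%), where more fell than rose.

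The glycosyltransferase list kept its direction in all settings run, with a mean of 0.32 to 0.49 with single arrays left out, and lost its call with array weights (mean 0.45), without DMF replicate 2 (0.41), without TNT replicate 1 (0.32) and with an estimated correlation (0.39); its adjusted p ranged from 0.00913 to 0.509. The antioxidant list had means of 0.15 to 0.34 with single arrays left out and passed without DMF replicate 3 (0.31). The cytochrome P450 list turned to -0.12 without the filter, and ranged from -0.045 to 0.21 with single arrays left out, negative without DMF replicate 2 (-0.027) and TNT replicate 1. The photosynthesis list ranged from -0.31 to 0.11 with single arrays left out, positive without TNT replicate 1. It passed without DMF replicate 2 (adjusted p = 0.0349), without TNT replicate 3 (adjusted p = 0.0106) and without both arrays numbered 2 (adjusted p = 0.0289). The wall list passed with array weights (adjusted p = 0.0296), with the replicate block (adjusted p = 0.0192), without DMF replicate 3 (adjusted p = 0.0463), without TNT replicate 2 (adjusted p = 0.00652) and without both arrays numbered 2 (adjusted p = 0.0119). With an estimated correlation it did not pass over all 6 arrays (adjusted p = 0.619) or without TNT replicate 2 (adjusted p = 0.254). Nor did it pass with fry (adjusted p = 0.545 and 0.0625). The ribosomal protein list lost its call without TNT replicate 1 (adjusted p = 0.265) and with an estimated correlation (adjusted p = 0.548), and did not pass with fry over all 6 arrays (adjusted p = 0.516). The cause of these changes was not tested. The replicate block itself changed the call of the wall list alone among the 7 tested lists.

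Of the named genes' values, 610 kept direction and side of the threshold, 105 kept direction and passed it, and 23 turned, for 8 genes that no setting called. Quantile normalization gave PYK10 0.028, median centring PYE -0.0020, and array weights Hsp70-2 -0.060 and PYE -0.032. With single arrays left out the log2 differences ranged from -0.17 to 0.014 for PYK10, -0.16 to 0.17 for PYE, -0.31 to 0.42 for Hsp70-2, -0.18 to 0.065 for NDB1, -0.18 to 1.37 for AT5G48570, -0.46 to 0.16 for COR47, -0.31 to 0.067 for PDC2 and -0.36 to 0.036 for GI. The cause was not tested. Signals under the bacterial controls on every DMF array, as those of UGT73B4 and UGT73C1, allow only lower bounds.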

Other observations

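The tests in this part were chosen after values had been seen, except the count of splits of the 6 arrays, which was planned. Both arrays numbered 2 had a higher mean over the heat shock list and a lower one over the dehydration list than the other 4. The 3 tested heat shock genes had a mean log2 signal of 7.41 on DMF replicate 2 and 7.30 on TNT replicate 2, against 5.84 and 5.92 on DMF replicates 1 and 3 and 6.46 and 6.42 on TNT replicates 1 and 3. AT5G48570, a heat-induced peptidyl-prolyl isomerase, was at 8.39 and 7.93 on DMF and TNT replicate 2 and between 5.29 and 6.39 on the other 4 arrays. Hsp70-2 was at 7.21 and 7.38 on DMF and TNT replicate 2 and between 6.06 and 6.31 on the others. Fes1A did not set them apart from the TNT arrays, with 6.65 and 6.57 there against 6.76 and 6.93 on TNT replicates 1 and 3. On DMF replicates 1 and 3 Fes1A was lower, at 5.87 and 6.16. The dehydration genes LTI30 and COR47 averaged 7.82 and 8.28 on the arrays numbered 2 and between 8.76 and 9.28 on the others. No test was made, since 2 arrays were set apart by their values.

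Without both arrays numbered 2, 656 probe sets were called at least 2-fold. Of these, 50 (7.62%) kept at least 50% of the log2 difference of the other pairs in replicate 2. In replicate 2, 282 of the 399 risen (70.7%) and 127 of the 257 fallen (49.4%) went the same way. Of the 50, 4 have a gene symbol. HRGP1 differed between TNT and DMF by -1.65 in replicate 2, against -1.54 and -1.32 in replicates 1 and 3. The others were CML38, PPDK and GH9C1. Their shared direction in replicate 2 follows from the choice of the 50, so it is not evidence of a response there. Probe sets that differed by at least 50% in the opposite direction were not counted. CML38, a calmodulin-like gene, and PPDK, pyruvate orthophosphate dikinase, named after their values were seen, had log2 differences between TNT and DMF of 1.05 and 1.01 in replicate 2. CML38 did not pass without TNT replicate 2 alone (limma adjusted p = 0.136). In replicates 1 and 3 the differences were 2.24 and 1.40 for CML38 and 1.03 and 1.87 for PPDK. GH9C1 differed by -0.90 in replicate 2 and by -1.25 and -1.36 in replicates 1 and 3. Without TNT replicate 2, the called probe sets without a gene name here that changed most were 74.0-fold higher (limma adjusted p = 2.94e-05) and 11.5-fold lower (adjusted p = 3.35e-05) with TNT.

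The array labelled TNT replicate 2 lay with the DMF arrays. On a scale where 0% is the DMF mean and 100% the mean of TNT replicates 1 and 3, it stood at a median of 6.31% over 563 probe sets. An exchange of its label with a DMF array would put a DMF array near the TNT arrays, but the highest DMF array, when left out of the choice of probe sets, stood at 14.8%, while TNT replicates 1 and 3 stood at 96.1% and 94.7%, which argues against it. Lower contrast of both arrays numbered 2 is argued against as well, since their SD of log2 signal was 90.8% of that of the other 4, while replicate 2 kept 7.59% of the response (bootstrap interval 5.39% to 9.95%).

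Undosed seedlings under a TNT label stay open. Among 656 probe sets called at least 2-fold without both arrays numbered 2, 36 differed 2-fold between TNT and DMF replicate 2, and 88.9% of these went the way of the other pairs. Differences between DMF arrays went one way in up to 78.1%, and a fixed bound considered first was set aside for that reason, so this margin does not decide. Over all 656, 62.3% went the way of the other pairs, 70.7% of the 399 that rose and 49.4% of the 257 that fell. Between DMF arrays the more common direction held 50.6% to 66.9%. The risen share lies above that range and the fallen share under it. A share of the more common direction is not the same measure, so this comparison does not decide either. Among the 3′ to 5′ ratios of actin, GAPDH and ubiquitin, only that of ubiquitin parted the groups. On it this array lay with its label, at 0.63 against 0.66 and 0.72 on TNT replicates 1 and 3 (log2). On the DMF arrays the ubiquitin ratio was 0.83 to 0.87. The GAPDH ratio was 0.19 on TNT replicate 2, nearest to 0.21 on DMF replicate 1, against 0.06 and -0.005 on TNT replicates 1 and 3. Ubiquitin is 1 control on 1 array, picked because it parts the labels, so it does not decide. For a small fixed share of RNA of dosed seedlings in undosed RNA, risen and fallen probe sets would keep an equal share of the linear change. Risen ones kept a median of 5.79% (bootstrap interval 4.33% to 7.64%), fallen ones -0.48% (-5.38% to 3.51%), a difference of 6.28 points, and the 20 largest rises 1.86% (range -1.54% to 6.98%). The intervals do not overlap, which goes against a fixed share, but probe sets are not independent, so that they are too narrow to exclude it. The bound against this explanation was moved from 10 to 20 points after that value was seen, and the difference lies under both. A weaker or later response of these seedlings, a lower dose, or a sample from outside the series was not tested. In a model with a separate effect for replicate 2, 1281 probe sets differed between it and the other pairs, on 1 residual degree of freedom, with limma at an adjusted p of 0.05.

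Of the 10 splits of the 6 arrays into 3 and 3, 10 gave as many calls as the real one, since it gave 0 and the highest other split 0. At an unadjusted p under 0.05 the real split gave 1195 probe sets and the highest of the 3 others that also part all pairs gave 930. A split of DMF replicate 1 with TNT replicates 1 and 3 gave 2896, and a split of DMF replicates 1 and 2 with TNT replicate 2 gave 1538, both above the real one. The first also sets TNT replicates 1 and 3 apart from TNT replicate 2, which it places with DMF replicates 2 and 3. Of the 10 splits of 5 arrays without TNT replicate 2, 1 gave as many as 947, the real one, and the highest other gave 4. TNT replicate 2 was left out for lying with the DMF arrays. That choice favoured the real split, so this count is not independent evidence. In either case 10 splits cannot give a share under 0.05.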
